A study of Homo sapiens with 5 samples.

How the data were processed

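Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on RD and RH18, established human cell lines of fusion-negative rhabdomyosarcoma, a soft tissue tumour with features of skeletal muscle. The labels list 5 samples: histone H3 acetylated at lysine 27 (H3K27ac) and input DNA in RD, and H3K27ac, MYF5 and input DNA in RH18. H3K27ac marks active enhancers and promoters, and MYF5 is a myogenic transcription factor of the basic helix-loop-helix family. Per the labels' protocols, cells were fixed in 1% formaldehyde for 12 minutes and sonicated, and chromatin was enriched with antibodies from Active Motif (H3K27ac) or Santa Cruz (MYF5). Each group held 1 library. No spread between replicates could be measured, and no difference between the lines has a replicate check. The series title also names MYOD, which was not analysed here.

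Peak lists of the 3 ChIP libraries were used, with 1 list per library. The 2 input samples had no list here and were not used as such. BWA 0.7.10, MACS2 2.1.0 and the genome build hg19 are named per the submitters' processing notes, which state no role, order, control or threshold. Per the deposited lists, each peak has a position, a fold enrichment (a ratio over the caller's local background at the summit), a −log10 p-value, a −log10 q-value, and a summit position. The deposited score is the −log10 p-value rescaled and truncated, with 1 entry off in the RH18 H3K27ac list, and it was not used further. All such values per peak are the authors', and were used to describe, rank or filter peaks within a list and to recover tags and background. The lowest −log10 p-value was 5.00 in the RD H3K27ac list, 7.09 in the RH18 H3K27ac list and 9.09 in the MYF5 list, so the lists did not end at a common threshold. Peak numbers skipped 49, 70 and 39 entries in these lists, in that order, which shows that entries had been removed before deposit. No entries of a list overlapped, so merging left every list as it was.

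Total reads per library were not given in the sources used here. The number of sequenced tags behind each summit was recovered from the deposited fold and p-value. Both values fit the formulas of MACS2, in which the fold is the pileup plus 1 over the background plus 1, and the p-value is the Poisson tail of the pileup given the background. A tag was worth 0.273 pileup units in the RD H3K27ac list, 0.832 in the RH18 H3K27ac list and 0.658 in the MYF5 list. Tags came out whole, within 0.1 tag, for 99.99% of RD peaks, 100.0% of RH18 H3K27ac peaks and 100.0% of MYF5 peaks, where chance gives 20.0%. More than 1 solution existed for 45.4%, 7.78% and 18.6% of peaks, and was resolved by the nearest whole tag. Among the 23575, 42797 and 9064 peaks with a single solution, the whole shares were 99.98%, 100.0% and 100.0%. On simulated peaks the step returned the tags of 99.2% of 4979 RD peaks, 99.9% of 5000 RH18 H3K27ac peaks and 100.0% of 5000 MYF5 peaks. Those peaks were written with the same formulas and with mostly low backgrounds. They check the code, and not the highest backgrounds reported below. The unequal worth of a tag compresses folds and p-values more in RD than in RH18, so neither was compared between lines. The stricter q-values used as alternatives were a common cut on both lists, and removed more regions from the RD list. The recovered background was divided by the lowest of its own list, and called raised at 4 times or more.

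H3K27ac regions of the lines were called shared where they overlapped by at least 1 bp, and a MYF5 peak was assigned by its summit. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Chance overlap was described by 200 seeded rotations of a list within each chromosome, and by 200 shifts of MYF5 summits by 20 to 100 kb. The share of regions holding a MYF5 summit was compared between shared and unshared regions with a two-sided Fisher's exact test, overall and within quintiles of width; such a test compares these libraries, not conditions. Odds ratios carry Woolf 95% intervals. Regions within 12.5 kb were joined into domains, which were ranked by the sum of fold times width, a ranking within a list that is not the super-enhancer procedure on reads. The overlap step, run on simulated points placed in RH18 regions at shares of 20.0%, 55.0% and 80.0%, returned those shares. Points outside regions were chosen with that same step, so this checks the code only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

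The main tests, a first set of alternatives and the rule for named regions were set before the data were examined. The recovery of tags and background was added later, with all tests and alternatives that use it, those without dense megabases or within quintiles of fold, and every alternative to the trend with MYF5 height. The rule took the 20 MYF5 peaks of highest fold, the 10 top domains of each line, and the 10 regions of highest fold found in one line alone, for each line. Coordinates are hg19 and counted from 1. No hg19 sequence or gene annotation was used here, so the planned comparisons of position relative to genes, of 13 gene lists and of E-box sequences were not run, and regions are named by position only. The alternatives set beforehand were stricter q-values, H3K27ac lists of equal length, autosomes alone, other overlap rules, joined regions and the MYF5 peaks of largest −log10 p-value alone. Others were other chance placements, regions of one width band, and other joining distances, rankings and numbers of domains.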

Results

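Active chromatin was mapped by H3K27ac ChIP-seq in RD and RH18, and binding of MYF5, a transcription factor of muscle progenitors, in RH18. Each of the 3 ChIP groups was 1 library, so the values below have no replicate error, and intervals cover counting error only. The RD H3K27ac list held 43159 regions covering 21.2 Mb, with a median width of 358 bp. The RH18 H3K27ac list held 46408 regions covering 32.5 Mb, with a median width of 474 bp. The MYF5 list held 11136 narrower peaks covering 3.50 Mb, with a median width of 256 bp. Median fold enrichment, as deposited by the authors, was 8.0 in the RD list, 13.98 in the RH18 H3K27ac list and 11.2 in the MYF5 list. Summits rested on a median of 85.0 recovered tags in RD H3K27ac, 57.0 in RH18 H3K27ac and 42.0 in MYF5. Folds of the lines are not on one scale, since a tag was worth less in the RD list.

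The first comparison asked how far active regions were the same in these lines. Of the RD H3K27ac regions, 25884 (59.97%, 95% interval 59.5 to 60.4%) overlapped an RH18 region. Of the RH18 regions, 20907 (45.1%, 44.6 to 45.5%) overlapped an RD region. Rotated lists gave 1.97% and 1.65%. Shared bases came to 12.6 Mb, or 30.7% of all bases covered in either line. Shared RH18 regions were wider than the unshared ones (median 692 against 376 bp) and had a higher fold (22.3 against 10.5). Shared RD regions were also wider (443 against 276 bp) and rested on more tags (109 against 59), while their median fold differed little (8.14 against 7.89). From the lowest to the highest decile of regions by recovered tags, the shared share ran from 25.9 to 92.8% in RD and from 16.6 to 87.2% in RH18. By fold it ran from 15.5 to 84.4% in RH18, but in RD it was 72.5% in the lowest decile, 50.4% in the fifth and 69.1% in the highest. Where an overlap of 50% of both regions was asked for, the shares were 27.5% of RD regions and 25.6% of RH18 regions. Each line had 1 H3K27ac library, so a difference between the lines includes any difference between the libraries.

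The RH18 regions of highest fold with no RD counterpart lay on 9 chromosomes. Of these 10 regions, 8 held a MYF5 summit, and 4 lay within 5 kb of an RD region. The highest, on chromosome 6 (169471407 to 169473700, fold 121, 350 tags), held 2 MYF5 summits, and the nearest RD region lay 13616 bp away. A region on chromosome 1 (232246178 to 232246832, fold 119) held 1 MYF5 summit and lay 138280 bp from the nearest RD region. A 5135 bp region on chromosome 17 (38706731 to 38711865, fold 115) held 2 and lay 2440 bp from an RD region. A region on chromosome 12 (81101425 to 81102944, fold 112) held 1 and lay 4242 bp from one. Of the corresponding 10 RD regions, 6 lay in one stretch of chromosome 8 (129873851 to 130326336), 1 of the 10 held a MYF5 summit, and 3 lay within 5 kb of an RH18 region. The highest RD region without an RH18 counterpart was on chromosome 8 (129958921 to 129959998, fold 48.4, 287 tags), 53261 bp from the nearest RH18 region. The next, on chromosome 12 (65927010 to 65928117, fold 45.4), lay 169 bp from one. Others on chromosome 8 lay at 129873851 to 129876024 (fold 42.9) and at 130325260 to 130326336 (fold 43.6), the latter 962 bp from an RH18 region. The RD region that held a MYF5 summit was on chromosome 12 (75944222 to 75945020, fold 42.6). A missing counterpart means no listed peak, and the lists ended at different p-values.

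The next comparison asked how often MYF5 sat in active chromatin of the line in which it was mapped. Of the 11136 MYF5 summits, 6150 (55.2%, 54.3 to 56.2%) lay inside an RH18 H3K27ac region, against 1.35% of rotated summits and 3.75% of summits shifted by 20 to 100 kb. The share within 500 bp of a region was 72.1%. Of the summits outside regions, 536 (10.8%) sat in a gap with RH18 regions ending within 500 bp on both sides; such gaps held 4.81% of all summits and 0.493% of shifted ones. The median distance from a MYF5 summit to the nearest RH18 H3K27ac summit was 370 bp. Seen from the H3K27ac regions, the share holding a MYF5 summit ran from 2.07% in the lowest decile by fold to 47.2% in the highest decile, where rotation gave 0.179% and 0.662%.

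In RD, a line without MYF5 data here, 4447 of the summits bound in RH18 (39.9%, 39.0 to 40.9%) lay inside H3K27ac regions, against 0.820% of rotated and 2.02% of shifted summits. Regions of both lines contained 3736 summits (33.5%), RH18 regions alone 2414 (21.7%), RD regions alone 711 (6.38%) and regions of neither line 4275 (38.4%). A summit outside a region may still lie beside one: 1183 summits sat in a gap with RD regions ending within 500 bp on both sides. Rotated summits fell inside regions of both lines in 0.510% of cases. MYF5 peaks in regions of both lines had a median fold of 9.997, below the 12.2 of peaks in neither. Their median recovered tags differed less, at 41.0 and 44.0. Within 500 bp of an RD region lay 62.9% of the summits. MYF5 binding in RD was not analysed here.

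Regions active in both lines held MYF5 summits more often than regions active in one. Among RH18 regions, 21.3% (20.8 to 21.9%) of the 20907 shared and 4.31% (4.07 to 4.57%) of the 25501 unshared held a summit, an odds ratio of 6.02 (5.62 to 6.45). Among RD regions, 14.5% (14.1 to 14.9%) of the 25884 shared and 2.53% (2.30 to 2.77%) of the 17275 unshared did, an odds ratio of 6.53 (5.90 to 7.23). Wide regions held summits more often, and shared regions were wider, so the comparison was repeated within quintiles of width. The odds ratios were then 2.87 to 4.38 in RH18 and 3.27 to 5.83 in RD. Within quintiles of fold, chosen after seeing the data like those of tags, they were 2.31 to 3.10 in RH18 and 4.54 to 9.33 in RD. Within quintiles of recovered tags they were 2.38 to 3.09 in RH18 and 2.19 to 5.18 in RD. The largest two-sided p of Fisher's exact test over the width quintiles was 1.8e-23 in RH18 and 7.2e-15 in RD, and over all such quintiles 8.1e-12 in RH18 and 1.1e-07 in RD, which compares these libraries and not conditions. In the widest RH18 quintile, from 974 bp up, 39.0% of shared and 18.2% of unshared regions held a summit. In RH18 regions of 1 to 3 kb the odds ratio was 2.88 (2.54 to 3.25), and without peaks of raised background in any list it was 3.47 (3.27 to 3.68).

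**Figure D1:**
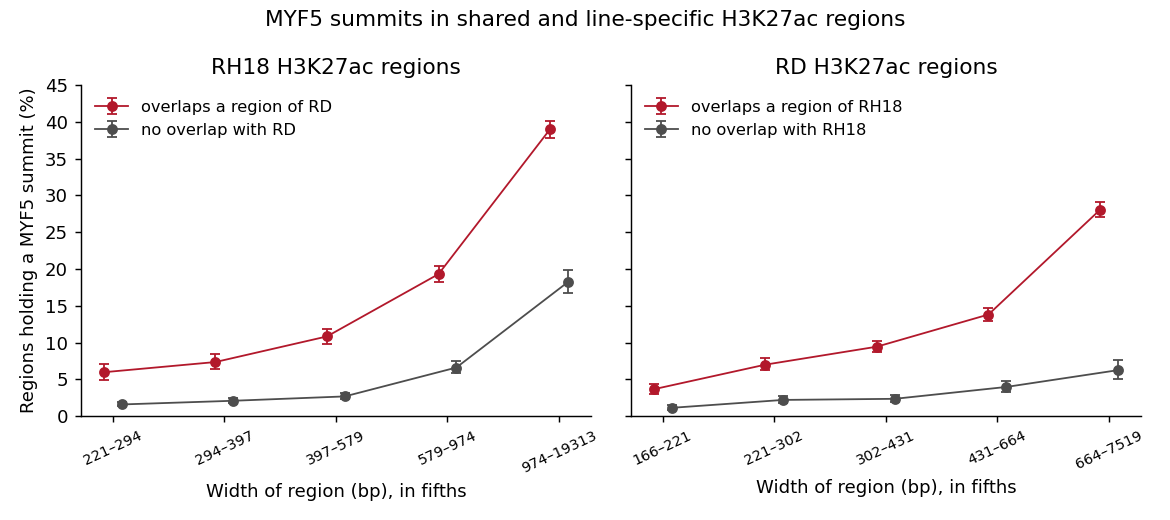
Share of H3K27ac regions holding a MYF5 summit (%, y axis) by quintile of region width (bp, x axis), for RH18 regions (left) and RD regions (right), split by overlap with a region of the other line. Points are shares with exact 95% binomial intervals; in the widest quintile they are 39.0% against 18.2% in RH18 and 28% against 6.27% in RD.

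MYF5 peaks of higher fold lay inside RH18 H3K27ac regions less often. The share was 72.9% (70.2 to 75.5%) in the lowest decile of 1114 peaks by fold and 37.6% (34.8 to 40.5%) in the highest, with a Spearman rho of -0.23 across peaks, which are not independent replicates. Inside RD regions the share ran from 49.0 to 28.4% (rho -0.15). In RH18 the difference was smaller with peaks ranked by recovered tags (61.0 to 43.4%, rho -0.08) or with summits within 500 bp counted (81.1 to 65.0%, rho -0.15). By tags the share was 57.0% in decile 2 and 57.7% in decile 7, so most of the fall lay above decile 7. With both changes together the difference was not detectable in RH18 (74.2 to 71.0%, rho -0.0082), and the share within 500 bp of RD regions rose with tags (57.4 to 69.7%, rho 0.0655). By fold, the share within 500 bp of RD regions had no trend detectable across peaks (rho -0.0085), with 63.7% in the lowest decile, 57.1% in decile 6 and 69.8% in the highest.

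**Figure D2:**
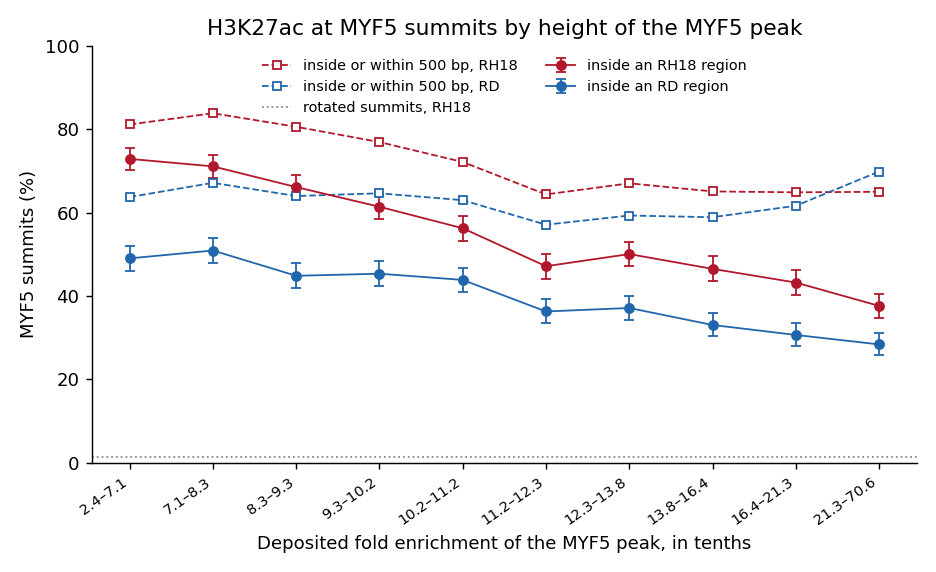
Share of MYF5 summits at H3K27ac (%, y axis) by decile of the deposited fold of the MYF5 peak (x axis), inside RH18 or RD regions (filled circles, exact 95% binomial intervals) and inside or within 500 bp (open squares); the dotted line is the mean of rotated summits in RH18. The share inside RH18 regions falls from 72.9 to 37.6%, while the share within 500 bp of RD regions is 63.7% in the lowest decile, 57.1% in decile 6 and 69.8% in the highest.

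The 20 MYF5 peaks of highest fold, from 58.3 to 70.6, rested on 178 to 237 tags. Of these, 2 lay inside an RH18 H3K27ac region and none inside an RD region, but 13 lay within 500 bp of an RH18 region and 13 within 500 bp of an RD region. The highest was on chromosome 10 (69524089 to 69524533, 216 tags), 30 bp from an RH18 region of fold 42.8 and 97 bp from an RD region. The peak on chromosome 20 (59709204 to 59710091, fold 68.96) lay 134 bp from an RH18 region of fold 80.4. The pair inside RH18 regions were on chromosome 10 (22518218 to 22518634, fold 68.5) and chromosome 2 (27273511 to 27274441, fold 59.9). More than 500 bp from H3K27ac in both lines lay 5 of the peaks. Their nearest RH18 regions were 501, 997, 1356, 67997 and 73383 bp away, the last at a peak on chromosome 6 (27560407 to 27560805, fold 59.9) and the one before at a peak on chromosome 14 (21081336 to 21082126, fold 62.1). No control immunoprecipitation was analysed here, so MYF5 binding and unspecific antibody signal were not separated at these peaks.

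MYF5 peaks were most crowded in the megabases of chromosome 12 from 48000001 and from 70000001, which held 73 and 66 peaks, and of chromosome 6 from 26000001 and from 27000001, which held 50 and 48. These bins were singled out after their values were seen. The chromosome 12 peaks were of low fold (medians 4.86 and 5.16), and the local background under them was 8.53 and 9.95 times the lowest of the list. The chromosome 6 peaks were of high fold (medians 21.7 and 24.2), with background at 1.0 and 1.005 times the lowest. In the same bins the RH18 H3K27ac list held 119 and 28 regions on chromosome 12, and 110 and 74 on chromosome 6. The RD list held 22 and 16 on chromosome 12, and 85 and 48 on chromosome 6.

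**Figure D3:**
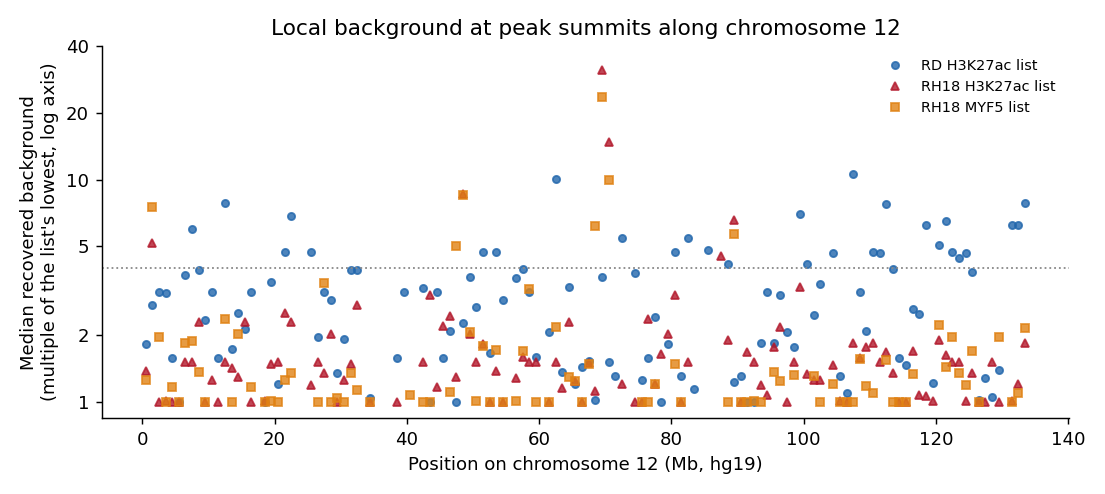
Median recovered background at peak summits per megabase of chromosome 12 (y axis, multiple of the lowest of each list, log scale) against position (x axis, Mb, hg19), with 1 point per list and megabase; the dotted line marks 4 times the lowest. Both RH18 lists rise together near 48 Mb (8.59 and 8.53) and 70 Mb (14.8 and 9.95), where the RD list is at 2.26 and 1.51, although the RD list exceeds the line in other bins. The RH18 lists part in the bin from 47000001, with 5.04 for MYF5 and 1.30 for H3K27ac. They also part from 68000001, with 6.16 over 4 MYF5 peaks and 1.12 for H3K27ac. The control is not stated, and the RH18 lists may share it, so their joint rise need not be independent.

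Stitched domains described the largest stretches of active chromatin. Joining gave 18842 domains in RH18 and 16671 in RD. The top 500 held 31.4% of the summed fold times width in RH18, over 22.0% of the covered bases, and 27.3% in RD, over 19.6%. Of the top 500 in RH18, 171 (34.2%, 30.0 to 38.5%) overlapped a top 500 domain of RD, against 1.43% by rotation, and 95.6% overlapped some RD region. MYF5 summits lay in 464 of the top RH18 domains (92.8%, 90.2 to 94.9%; rotation 12.4%) and in 25.3% of the others. In RD the figures were 409 (81.8%, 78.1 to 85.1%; rotation 8.34%) and 25.5%. The top domains were far longer (median span 32.7 kb in RH18) than the others (1.25 kb). The rotations take this into account for the top domains only. No rotation share was available for the others, so the contrast with them is not adjusted for length.

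Among the 10 highest domains of each line, all 10 in RH18 and 9 in RD held a MYF5 summit. The first in RH18 spanned 103 kb of chromosome 10 (80861164 to 80964276, mean fold 56.4) with 8 MYF5 summits. It was followed by 96.4 kb of chromosome 16 (70715403 to 70811805) with 9, and by 69.6 kb of chromosome 22 (19831850 to 19901409) with 10. The RD domain that the last of these overlapped had rank 4258. The first in RD spanned 65.7 kb of chromosome 11 (125970447 to 126036179, mean fold 24.1) with 5 MYF5 summits, and the second 51.3 kb of chromosome 7 (129984919 to 130036238) with 8. A stretch of chromosome 14 ranked 5 in RH18 (69013757 to 69080608) and 7 in RD (69013825 to 69079713), with 11 MYF5 summits by either set of bounds. The RD domain without a summit was on chromosome 9 (97622284 to 97685798). In each line, 6 of the 10 overlapped a top 500 domain of the other. These ranks hold within each list, and the folds behind them were compressed to different degrees.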

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

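The background tests of chromosome 12 were chosen after the result was seen. The local background recovered from the RH18 H3K27ac list was raised in 5 megabases of chromosome 12 in which the RD list was not, and in which both RH18 lists had at least 10 peaks. Its median over the lowest of the list was 5.18 from position 1000001, 8.59 from 48000001, 31.1 from 69000001, 14.8 from 70000001 and 6.56 from 89000001. The RD values in these bins were 2.72, 2.26, 3.65, 1.51 and 1.22. The input samples had no list here, and this signal lay outside the planned comparisons.

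The megabases from 48000001 and 70000001 were also the most crowded in MYF5 peaks, with 73 and 66. Their median MYF5 folds were 4.86 and 5.16, against 11.2 over the whole list, while their median tags were 77.0 and 78.0. The median background under those MYF5 peaks was at least 8.53 times the lowest, and a bias shared by all libraries is opposed by the RD background, which was at most 2.26 times its lowest. A candidate explanation is therefore a gain of these stretches in RH18 that lifts both background and MYF5 tags, so that lower folds pass the threshold. It leaves open why MYF5 peaks numbered 94.6 per 100 RH18 H3K27ac regions in the pair of bins, against 23.8 elsewhere. The pair was uneven, with 73 and 66 MYF5 peaks beside 119 and 28 RH18 regions. The other 3 raised bins held fewer MYF5 peaks, 31, 24 and 28, beside 52, 23 and 14 RH18 regions. Per region, each of them also exceeded the 23.8 per 100. The 24 lay from 69000001, at the highest background. Copy number was not measured, and no biological explanation was tested.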

How the results depend on the processing

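Of 65 alternatives run, 35 values stayed within the interval or on their side of 1 or 0, 27 moved, 2 no longer differed from 0 and 1 turned direction; no odds ratio interval reached 1. The last 3 concern the rho of MYF5 height. With summits within 500 bp counted it was -0.0085 for RD regions by fold, -0.0082 for RH18 regions by tags, and 0.0655, turned from negative, for RD regions by tags. The settings without raised background, without dense megabases, by quintiles of fold or tags, and with most tags, and all those on MYF5 height, were chosen after seeing the data. In the shares of regions shared between lines, RH18 first and RD next, a −log10 q of at least 5 gave 43.5 and 60.5%, of at least 10 gave 36.9 and 65.8%, lists of equal length 47.4 and 59.04%, reciprocal overlap 25.6 and 27.5%, summits inside regions 42.2 and 57.7%, regions joined within 1000 bp 51.4 and 63.5%, and the 20000 regions with most tags 53.1 and 67.8%. In the shares of MYF5 summits, RH18 regions first and RD regions next, any overlap gave 64.1 and 55.5%, and a distance of 500 bp 72.1 and 62.9%. The 5000 MYF5 peaks of largest −log10 p-value gave 47.6 and 33.9%. The share in RH18 was 54.1% without dense megabases, and the share in RD 36.7% at a −log10 q of at least 10. The share of top RH18 domains shared with RD was 28.8% with joining at 5000 bp, 41.0% at 25000 bp, 26.0% for the top 200 and 40.4% for the top 1000. Random placement moved the chance overlap little (1.66%). The odds ratio of 3.47 without raised background came with 13768 RD regions left out, which turns shared RH18 regions into unshared ones; leaving out such RH18 regions alone gave 6.03. A −log10 q of at least 10 kept 29466 of 43159 RD regions but 44460 of 46408 RH18 regions. Its shares therefore come from lists cut to unlike degrees. The cause of other changes was not tested. A −log10 q of at least 5 removed RD peaks alone, and the setting of 1 summit per merged region changed nothing, so neither tests the MYF5 share in RH18. Alternatives that need gene annotation or sequence were not run, including domains without promoter regions. The lists ended at different thresholds and library depth is unknown, which limits what an unshared region shows.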

Other observations

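All tests below were chosen after the data were examined, and only the prediction for the one at the lowest background was written before its result was seen. MYF5 peaks were spread unevenly over chromosomes. Their number per 100 RH18 H3K27ac regions was 24.0 over the genome, 34.96 on chromosome 20, 32.9 on chromosome 7 and 31.2 on chromosome 8, against 11.2 on chromosome 4, 12.3 on chromosome X and 12.9 on chromosome 9. The mean MYF5 background, as a multiple of the lowest, was also higher on the first of these (2.35, 2.02 and 1.74) than on the latter (1.12, 1.09 and 1.28). It was highest on chromosome 12, at 5.59, with 28.8 MYF5 peaks per 100 regions, and next on chromosome 19, at 2.51, with 23.01. A mean can be raised by a few peaks, and background and number were not separated. RH18 had 1.62 H3K27ac regions per RD region on chromosome 22 and 0.727 on chromosome 4, against 1.08 over all chromosomes. Unshared regions made up 16.4% of RD regions on chromosome 19 and 57.5% on chromosome 4, the lowest and highest of the 23 chromosomes compared.

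On chromosome 6, the adjoining megabases from 26000001 to 28000000 held 98 MYF5 peaks with a median fold of 22.4, against 11.2 elsewhere, and 54 of these were among the highest decile of all MYF5 peaks. Raised background is opposed by its median of at most 1.01 times the lowest. More H3K27ac regions with MYF5 in the usual proportion stay open by the prediction written for it, since the stretch was picked by its MYF5 peaks. The stretch had 53.3 MYF5 peaks per 100 RH18 regions, against 23.9 elsewhere. Of 224 other megabases with at least 50 RH18 regions, 5 exceeded its lower bin (45.5). Its higher bin (64.9) exceeded the highest of them (61.3, on chromosome 12 from 48000001). Both bins lay above the upper quartile of those megabases (24.7). This explanation concerns the number of peaks and does not address their higher fold. An RD domain in this stretch (26172316 to 26235421, ranked 19, singled out after its values were seen) held 16 MYF5 summits. It overlapped an RH18 domain of rank 21. Binding by MYF5 and antibody signal at very active genes may both give such a cluster, and no control immunoprecipitation was analysed here that would separate them.

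The lower share of MYF5 summits inside H3K27ac regions at higher fold may be technical, and 3 explanations were tested alone and 2 of them together. If fold followed only the local background, the trend should vanish among the 3932 peaks at the lowest background, but rho there was -0.15 (95% interval -0.18 to -0.12). Neither region edges alone (rho -0.15 when summits within 500 bp counted as inside) nor dense megabases (rho -0.25 outside them) account for all of the trend by fold in RH18 regions; in RD regions edges alone may, since the 500 bp rule left rho at -0.0085 (-0.03 to 0.01), and at 0.04 (0.01 to 0.08) at the lowest background. Background and edges together stay open for RH18 regions, since with peaks ranked by tags and summits within 500 bp counted rho was -0.0082 (-0.03 to 0.01) over all peaks, but -0.09 (-0.12 to -0.06) among those at the lowest background. Unspecific antibody signal at the tallest peaks and MYF5 binding away from H3K27ac also stay open, and neither was tested.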
